A study of Mus musculus with 10 samples.

How the data were processed

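Whole kidneys of mice at postnatal day 21 were profiled by RNA sequencing in 10 libraries, 4 from wild-type animals (WT), 3 from animals with Pkd2 deleted by the Pkhd1Cre driver (SM) and 3 from animals with the same deletion and no functional miR-21 gene (DM). Groups were taken from the genotype labels, and each library carries its own animal number. Kidneys were frozen, RNA was extracted with a miRNeasy kit and libraries were made with a stranded total RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, TopHat2 2.0.12, Cufflinks, featureCounts, Subread 1.4.6 and edgeR 3.2.4 with the genome build mm10, and the role of each tool is not given in the sources used here.

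The authors deposited 3 tables of their own comparisons, SM against WT, DM against WT and DM against SM, and no value per library was analysed here. Each table held 30431 rows, of which 23276 carried a gene name and 7155 were assembled loci without one. Per the file headers, each deposited row gives a log2 fold change, an average log2 CPM, the count scaled to library size, a likelihood ratio score from edgeR's generalized linear model, its p-value and its false discovery rate. Testing on the files showed that the deposited average log2 values were identical in the 3 tables, that the log2 fold changes of the first pair of tables subtract to those of the third, that each deposited p-value is the chi-square tail of its score, and that the deposited adjusted p-value is the Benjamini-Hochberg value over all 30431 rows. The tables were therefore read as contrasts of a single fit of all 10 libraries without a filter on low values. Library sizes and the authors' normalization factors are not given in the sources used here, so the depth behind each value is unknown and no counting interval is given.

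The planned test on counts could not be run on such tables, so the planned replacement was used, the authors' deposited adjusted p below 0.05 from edgeR's likelihood ratio test. Levels per group in CPM were computed from the deposited average and the fold changes. An implied standard error (SE) was computed as the absolute log2 fold change divided by the square root of the likelihood ratio score. It is approximate, and for rows close to the lowest level it is not reliable. In data simulated for SM against WT with known spread, over 15135 genes, the implied SE was 1.00 times the true SE in the median, with a 5th percentile of 0.989 and a 95th percentile of 1.02. At the dispersion simulated, 125 of 200 genes changed by 1 on the log2 scale were recovered and 11 unchanged genes were called. The simulated test was given the true dispersion. Its values therefore do not show the error of the implied SE, or of the calls, where the dispersion is estimated from the libraries.

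Gene lists (28, of which 27 had measured members) were fixed before the data were examined. Each was tested with limma 3.58.1 (cameraPR, R 4.3.3) on the signed root of the likelihood ratio, with a preset correlation between genes of 0.01, against the 15135 rows with an average of at least 1 CPM, and adjusted by Benjamini-Hochberg over 81 tests. That background was chosen after the tables were seen, and all rows were the alternative. A correlation cannot be estimated from tables without libraries, so a preset of 0.05 was the stricter alternative. The list of genes of the mitochondrial genome had 0 measured members. Tested on simulated data for SM against WT, a list raised by 1 unit had an adjusted p of 1.5e-04 and 0 of the other 26 lists were called. The simulated genes were independent, so false calls in lists whose members vary together were not tested. Members that passed are also counted with p adjusted over the list alone. Another 5 lists, of hepatocyte, adrenal gland, pancreas, skeletal muscle and fat markers, were written after the tables were seen.

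Gene positions came from GENCODE mouse release 21 on GRCm38, the assembly that mm10 names, and 22851 of the 23276 named rows were matched by symbol or by a unique synonym. Sites for miR-21-5p were searched in the longest annotated 3′ UTR of 13447 protein-coding genes with an average of at least 1 CPM. The difference in median log2 fold change between genes with and without the word ATAAGCT was ranked, 2-sided, among the 419 other permutations of the same 7 bases. A first version of that test measured the distance of each difference from 0. It was replaced by the planned rank after its result had been seen, because the control words were not centred on 0, and both values are given. For neighbourhoods, the share of genes with p below 0.05 within 10 Mb of a locus was compared with windows of as many neighbouring genes elsewhere. Simulated for DM against SM over 13918 genes, a window with 10 percent of its genes changed lay at the 100th percentile and an unchanged window at 84.7. The simulated p-values were independent between neighbours, so the test may find less in real data. For the word rank, simulated for DM against SM over 13000 genes, a planted log2 shift of 0.05 gave 0.00476 and no shift gave 0.957. Smaller shifts were not simulated, and the simulated words fell on genes independently.

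Genes are named by a rule fixed before the data were examined. It takes Pkd2, the miR-21 gene and its host Vmp1. Then come the 6 higher and 6 lower named genes with the largest log2 fold change past the threshold. They are at 1 CPM or more in a group, and Gm numbers, Rik names, other provisional symbols and pseudogenes are left out. Each list with at least 3 members past the threshold gives the 2 to 4 members with the smallest adjusted p. Reported miR-21 targets give 4 in every case. Only a part of the genes so taken is printed here. Alternatives covered a least fold change, rows with at least 1 CPM, rows with names, rows without particular gene groups, the list background and correlation, and the choice of sites and control words. Interferon-induced families were picked by symbol and from the interferon response list, so members with other symbols may remain. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.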

Results

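RNA was measured in whole kidneys of 10 mice at postnatal day 21. The animals were 4 wild types (WT), 3 with Pkd2 deleted by Pkhd1Cre, a Cre driver active in the collecting duct (SM), and 3 with that deletion that also lacked miR-21 (DM). Pkd2 encodes polycystin-2, and its loss in tubule cells causes polycystic kidneys. The comparisons ask how the kidney transcriptome differs with loss of Pkd2, and how it differs further when miR-21 is also missing. All log2 fold changes, p-values and adjusted p-values of single genes are those of the authors' deposited table of each comparison, from edgeR's likelihood ratio test. The tables carry no value per library, so the error given is the SE implied by the test, and the depth of the libraries is unknown.

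Pkd2 (chromosome 5, 104459450 to 104505819, GRCm38) had a log2 fold change of -0.41 (implied SE 0.20, adjusted p = 0.179) in SM against WT and of -0.49 (implied SE 0.20, adjusted p = 0.0838) in DM against WT, in the authors' deposited tables. Neither value passed the threshold. The tissue was whole kidney and the row covers the whole gene, so the value includes transcripts of cells outside the driver's range. The miR-21 gene lies at 86584067 to 86584158 on chromosome 11, within a 3′ UTR exon of a transcript of Vmp1 (86583865 to 86683836). Its row stood at the lowest level in the authors' deposited tables and checks nothing. For Vmp1 the authors' deposited tables gave 0.26 (implied SE 0.30, adjusted p = 0.729) in SM against WT, 1.33 (implied SE 0.30, adjusted p = 2.15e-04) in DM against WT, and 1.07 (implied SE 0.32, adjusted p = 0.32) in DM against SM.

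Loss of Pkd2 was accompanied by higher tubular injury, macrophage, matrix and mitotic genes and lower proximal tubule, thick ascending limb, distal convoluted tubule and intercalated cell genes. Of the 23 tubular injury genes, 22 rose in SM against WT in the authors' deposited table and 23 did so adjusted over the list alone (median log2 fold change 2.11, camera adjusted p = 4.4e-34). Among them were Lcn2, the iron-binding protein NGAL, at 5.77 (implied SE 0.34, adjusted p = 2.65e-60 in the authors' deposited table) and Havcr1, the injury marker KIM-1, at 7.73 (implied SE 0.70). Macrophage genes rose for 25 of 27 measured members in the authors' deposited table, 25 adjusted over the list alone (median 2.28, camera adjusted p = 3.98e-35). Cd14 stood at 3.01 (implied SE 0.26) and Mrc1 at 2.55 (implied SE 0.22) in the authors' deposited table. Of 28 fibrillar matrix and fibrosis genes, 24 rose in the authors' deposited table and 27 adjusted over the list alone (median 1.58, camera adjusted p = 1.65e-23), including Timp1, an inhibitor of matrix metalloproteases, at 5.24 (implied SE 0.50) and Tgfb2 at 2.35 (implied SE 0.26).

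Mitotic genes rose for 25 of 27 members in the authors' deposited table of SM against WT, 27 adjusted over the list alone (camera adjusted p = 3.58e-09), with Ndc80, a kinetochore protein, at 1.87 (implied SE 0.41). Of 24 S phase genes, 14 rose in the authors' deposited table and 18 adjusted over the list alone (camera adjusted p = 2.36e-05). The helicase subunit Mcm7 stood at 0.90 (implied SE 0.19) in the authors' deposited table. Among p53 and apoptosis genes, 7 of 22 rose in the authors' deposited table, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00317), led by Eda2r at 3.30 (implied SE 0.41). Wnt, Notch and Hedgehog targets rose for 12 of 23 members in the authors' deposited table, 13 adjusted over the list alone (camera adjusted p = 2.69e-06). Sox4 stood at 1.81 (implied SE 0.22) and Myc at 1.84 (implied SE 0.36) in the authors' deposited table. Principal cell genes, which mark the collecting duct, rose for 11 of 16 members in the authors' deposited table, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.36e-05). The water channel Aqp4 stood at 1.73 (implied SE 0.22) in the authors' deposited table. Among cAMP response genes 6 of 20 rose in the authors' deposited table, with 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0133). Fos stood at 2.87 (implied SE 0.39) and Junb at 1.69 (implied SE 0.21) in the authors' deposited table. The list's adjusted p = 0.0602 at a preset correlation of 0.05.

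Proximal tubule genes fell for 20 of 26 members in the authors' deposited table of SM against WT, 24 adjusted over the list alone, and 1 rose in either count (median -1.16, camera adjusted p = 1.5e-11). The organic anion transporter Slc22a6 stood at -1.68 (implied SE 0.22) and Gatm, an enzyme of creatine synthesis, at -1.82 (implied SE 0.32) in the authors' deposited table. Nuclear genes of oxidative phosphorylation fell for 26 of 27 members in the authors' deposited table and 27 adjusted over the list alone (median -0.95, camera adjusted p = 2.54e-11). Cox5a stood at -1.26 (implied SE 0.28) in the authors' deposited table. Of 28 fatty acid oxidation and PPAR-alpha genes, 13 fell and 1 rose in the authors' deposited table, with 16 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.15e-05), among them Fabp1 at -3.09 (implied SE 0.75). Fabp1 fell further than Gatm, the lowest proximal tubule gene, and the list's median implied SE was 0.26. Whether liver RNA in WT, taken up below, contributes to the value of Fabp1 was not tested. In the distal nephron, 7 of 11 distal convoluted tubule genes fell and 1 rose in the authors' deposited table, 7 and 2 adjusted over the list alone (camera adjusted p = 1.04e-05). Pvalb stood at -3.68 (implied SE 0.42) in the authors' deposited table. Thick ascending limb genes fell for 6 of 13 members in the authors' deposited table, 8 adjusted over the list alone (camera adjusted p = 1.22e-04). Egf stood at -2.18 (implied SE 0.35) in the authors' deposited table. Intercalated cell genes fell for 5 of 13 members in the authors' deposited table, 6 adjusted over the list alone (camera adjusted p = 0.00195). The proton pump subunit Atp6v1g3 stood at -1.06 (implied SE 0.20) in the authors' deposited table. Markers of hepatocytes, in a list written after the tables were seen, also fell for 23 of 40 members and rose for 2 in the authors' deposited table of SM against WT, 24 and 4 adjusted over the list alone (median -1.41 among the 29 members above 1 CPM).

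Podocyte genes did not pass as a list in SM against WT (camera adjusted p = 0.276), and 4 of 14 fell in the authors' deposited table, 4 adjusted over the list alone. Nphs1 stood at -0.81 (implied SE 0.22) in the authors' deposited table. Neutrophil genes rose for 3 of 12 members in the authors' deposited table, 5 adjusted over the list alone. Csf3r stood at 1.58 (implied SE 0.30) in the authors' deposited table. T, B and NK cell genes rose for 3 of 21 members in the authors' deposited table, 3 adjusted over the list alone. Il7r stood at 1.66 (implied SE 0.46) in the authors' deposited table. As lists these had camera adjusted p = 0.17 and 0.612. Among fibroblast and mural cell genes 4 of 16 rose and 1 fell in the authors' deposited table, 6 and 1 adjusted over the list alone (camera adjusted p = 0.053, and 0.0115 with all rows as background). Mgp stood at 2.11 (implied SE 0.44) and Ecm1 at -1.34 (implied SE 0.23) in the authors' deposited table. Of 23 interferon response genes 3 rose in the authors' deposited table, 3 adjusted over the list alone (camera adjusted p = 0.0695, and 0.0123 with all rows as background). Mx1 stood at 2.33 (implied SE 0.70) in the authors' deposited table. The blood list, with 4 members above 1 CPM, had 1 of 9 members lower in the authors' deposited table, 1 adjusted over the list alone (camera adjusted p = 0.0498, with adjusted p = 0.0682 at a preset correlation of 0.05 and 0.17 with all rows as background). Lists of cilium genes (camera adjusted p = 0.864, 1 of 30 higher and 1 lower), glycolysis (0.252, 2 of 16 lower), endothelium (0.438, 0 of 16 called), sex-linked genes (0.942, 0 of 5 called) and the perturbed loci (0.8, 0 of 5 called) did not pass, with member counts from the authors' deposited table. Adjusted over the list alone, 1 perturbed locus was higher and the counts of the other lists were equal to those over all genes. With a median implied SE of 1.74 the sex-linked list cannot show whether the sexes were balanced between groups. Of 38 reported miR-21 targets, 10 rose and 1 fell in the authors' deposited table of SM against WT, 13 and 2 adjusted over the list alone (camera adjusted p = 0.00204). Tpm1 stood at 1.77 (implied SE 0.24) and Stat3 at 0.94 (implied SE 0.20) in the authors' deposited table.

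In total 4248 of 30431 rows passed in SM against WT in the authors' deposited table, 2394 higher and 1854 lower. The largest increases among named genes were Wnt7a at 8.23 (implied SE 0.74), Havcr1, the neuronal RNA-binding protein gene Elavl4 at 7.11 (implied SE 0.67), the keratin Krt17 at 6.51 (implied SE 0.68), Il1f6 at 5.97 (implied SE 0.60) and the chemokine Cxcl5 at 5.84 (implied SE 0.98) in the authors' deposited table. The largest decreases were Serpina3k at -11.09 (implied SE 2.17), Mug1 at -8.82 (implied SE 1.82), albumin (Alb) at -8.66 (implied SE 1.49), Ugt2b38 at -8.59 (implied SE 1.5), Cyp3a11 at -8.48 (implied SE 1.91) and Ahsg at -8.40 (implied SE 1.70) in the authors' deposited table. Serpina3k, Mug1, Alb, Cyp3a11 and Ahsg are known as liver genes.

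**Figure D1:**
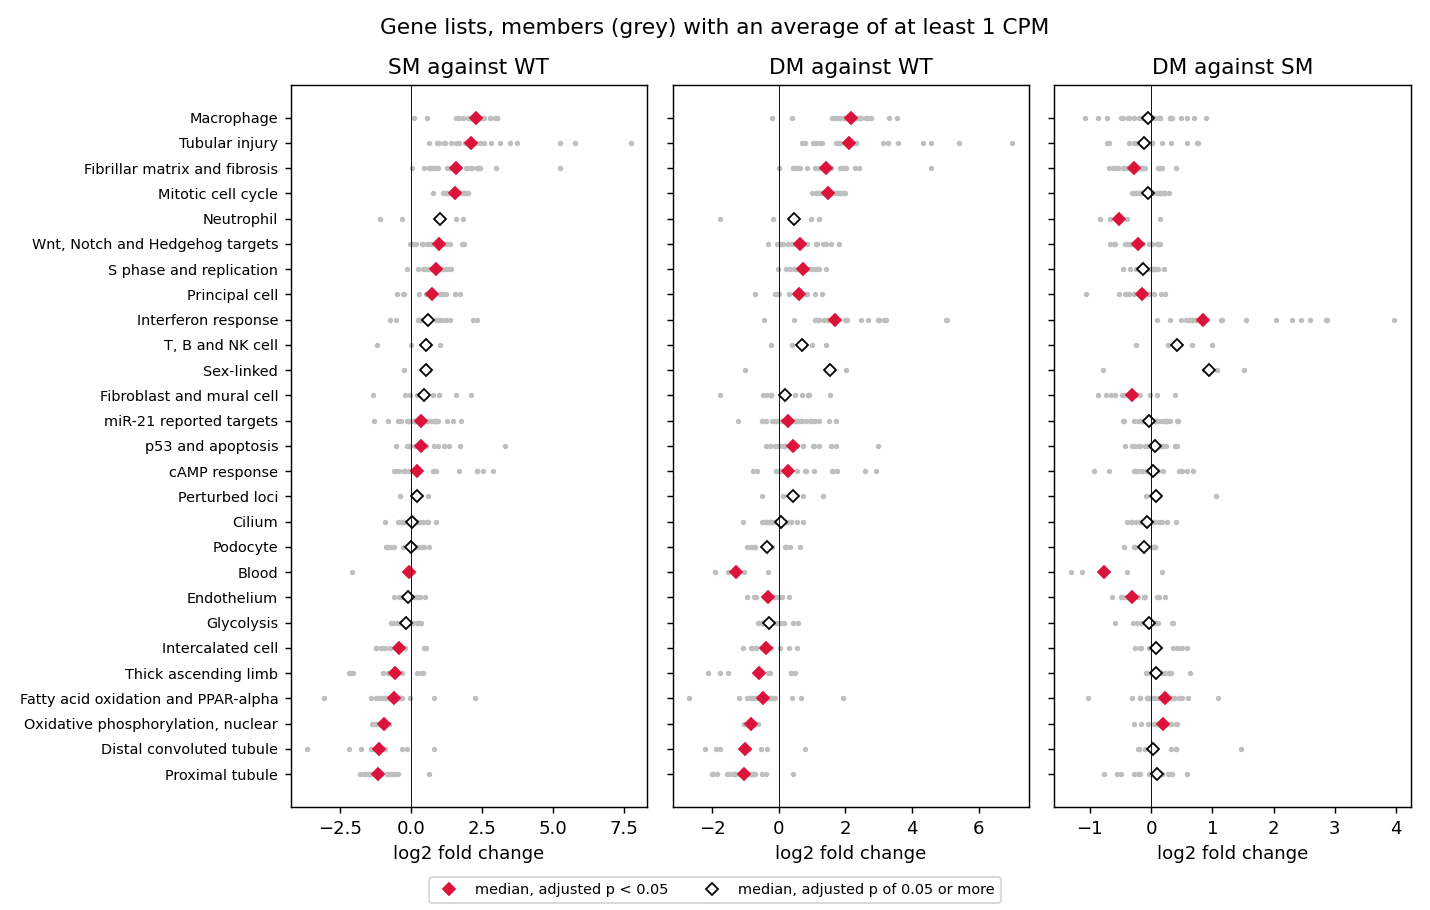
Log2 fold changes of list members (grey points) and their medians (diamonds, red where the camera adjusted p is below 0.05) in the 3 comparisons, for members with an average of at least 1 CPM. The macrophage and tubular injury lists have medians of 2.28 and 2.11 in SM against WT, and the interferon response list has a median of 0.85 in DM against SM.

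Kidneys that lacked both Pkd2 and miR-21 differed from wild type in the injury, macrophage and matrix lists too, and interferon genes were higher as well. All 23 tubular injury genes rose in DM against WT in the authors' deposited table, 23 adjusted over the list alone (median 2.12, camera adjusted p = 1.09e-35). Lcn2 stood at 5.42 (implied SE 0.33) in the authors' deposited table. Macrophage genes rose for 24 of 27 members in the authors' deposited table, 25 adjusted over the list alone (camera adjusted p = 1.83e-36). C1qa stood at 2.70 (implied SE 0.25) in the authors' deposited table. Matrix genes rose for 22 of 28 members in the authors' deposited table, 23 adjusted over the list alone (camera adjusted p = 4.26e-18). Timp1 stood at 4.56 (implied SE 0.49) in the authors' deposited table. Interferon response genes rose for 17 of 23 members in the authors' deposited table, 21 adjusted over the list alone (median 1.70, camera adjusted p = 3.26e-09). The chemokine Cxcl10 stood at 5.05 (implied SE 0.82) and the GTPase Gbp2 at 5.02 (implied SE 0.93) in the authors' deposited table. Among T, B and NK cell genes 10 of 21 rose in the authors' deposited table, 11 adjusted over the list alone, with Cd8b1 at 4.67 (implied SE 0.97) and Gzmb at 4.65 (implied SE 1.01), although the list, with 6 members above 1 CPM, had camera adjusted p = 0.17 (3.65e-07 with all rows as background).

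In DM against WT, mitotic genes rose for 22 of 27 members in the authors' deposited table, 27 adjusted over the list alone (camera adjusted p = 1.08e-09). Top2a stood at 1.98 (implied SE 0.49) in the authors' deposited table. S phase genes rose for 8 of 24 members in the authors' deposited table, 14 adjusted over the list alone (camera adjusted p = 1.19e-04). The p53 list had 7 of 22 members higher in the authors' deposited table, 8 adjusted over the list alone (camera adjusted p = 8.15e-04). Cdkn1a stood at 1.57 (implied SE 0.29) in the authors' deposited table. Wnt, Notch and Hedgehog targets rose for 8 of 23 in the authors' deposited table, 10 adjusted over the list alone (camera adjusted p = 1.19e-04), cAMP response genes for 8 of 20 with 1 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 0.00354), and principal cell genes for 5 of 16 with 1 lower, 9 and 1 adjusted over the list alone (camera adjusted p = 0.004). Reported miR-21 targets rose for 11 of 38 members with 1 lower in the authors' deposited table, 15 and 1 adjusted over the list alone (camera adjusted p = 7.42e-04). Stat3 stood at 1.20 (implied SE 0.20) in the authors' deposited table.

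Proximal tubule genes fell for 18 of 26 members in the authors' deposited table of DM against WT, 23 adjusted over the list alone (median -1.05, camera adjusted p = 4.1e-12). Gatm stood at -2.0 (implied SE 0.32) in the authors' deposited table. Oxidative phosphorylation genes fell for 17 of 27 in the authors' deposited table, 26 adjusted over the list alone (camera adjusted p = 2.56e-09), and fatty acid oxidation genes for 8 of 28 with 1 higher, 10 and 1 adjusted over the list alone (camera adjusted p = 5.61e-04). Lower counts of the distal nephron in the authors' deposited table were 7 of 11 for the distal convoluted tubule with 1 higher, 8 and 1 adjusted over the list alone (camera adjusted p = 4.45e-05), 5 of 13 for the thick ascending limb, 5 adjusted over the list alone (camera adjusted p = 9.24e-04), and 4 of 13 for intercalated cells, 4 adjusted over the list alone (camera adjusted p = 0.0133). Endothelial genes fell for 4 of 16 in the authors' deposited table, 4 adjusted over the list alone (camera adjusted p = 0.0151, and adjusted p = 0.0602 at a preset correlation of 0.05). The sialomucin Emcn stood at -0.95 (implied SE 0.23) in the authors' deposited table. Podocyte genes fell for 4 of 14 in the authors' deposited table, 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0664, and 0.0368 with all rows as background). Nphs1 stood at -0.95 (implied SE 0.22) in the authors' deposited table. The blood list fell (camera adjusted p = 0.00144, median -1.29 over 4 members above 1 CPM and -0.15 over all 9) with 1 of 9 members past the threshold in the authors' deposited table, 1 adjusted over the list alone. Hepatocyte markers fell for 23 of 40 members and rose for 3 in the authors' deposited table here too, 24 and 3 adjusted over the list alone (median -1.31 among those above 1 CPM). The neutrophil (camera adjusted p = 0.629, 1 of 12 higher and 2 lower), fibroblast and mural cell (0.761, 3 of 16 higher and 1 lower), glycolysis (0.17, 1 of 16 lower), cilium (0.607, 1 of 30 higher and 1 lower), sex-linked (0.726, 0 of 5 called) and perturbed loci (0.333, 2 of 5 higher) lists did not pass, with member counts from the authors' deposited table. Adjusted over the list alone, 6 fibroblast and mural cell genes were higher and 1 lower, 0 glycolysis genes were called, 2 perturbed loci were higher and 1 lower, and the remaining counts were equal to those over all genes.

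In total 4100 rows passed in DM against WT in the authors' deposited table, 2299 higher and 1801 lower. The largest increases were the cell cycle inhibitor gene Cdkn2a at 8.59 (implied SE 0.91), H2-Eb2 at 8.41 (implied SE 1.47), Wnt7a at 7.42 (implied SE 0.73), Havcr1 at 7.02 (implied SE 0.68), Gbp10 at 6.99 (implied SE 1.54) and Elavl4 at 6.81 (implied SE 0.67) in the authors' deposited table. The largest decreases were Mug1 at -8.82 (implied SE 1.74), Ugt2b38 at -8.80 (implied SE 1.49), Cyp2c70 at -8.37 (implied SE 1.89), Ahsg at -7.05 (implied SE 1.58), Alb at -7.01 (implied SE 1.38) and Tat at -6.46 (implied SE 1.64) in the authors' deposited table.

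Both comparisons with WT were set side by side. Rows higher in both comparisons with WT numbered 1804 and rows lower in both 1233 in the authors' deposited tables, and 2 rows passed in opposite directions. Independent lists of those sizes would share 181 and 110 rows. Simulated unchanged groups shared a mean of 0 rows, a value that leaves out the effects and does not show how much of the sharing comes from the WT libraries. Across 15135 rows, which are not independent replicates, the correlation of the 2 sets of log2 fold changes was 0.887, against 0.429 for simulated unchanged groups that share the WT libraries (100 draws), and the covariance was 0.553 against 0.0388. The WT libraries could not be split, so part of the excess may come from the shared controls.

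**Figure D2:**
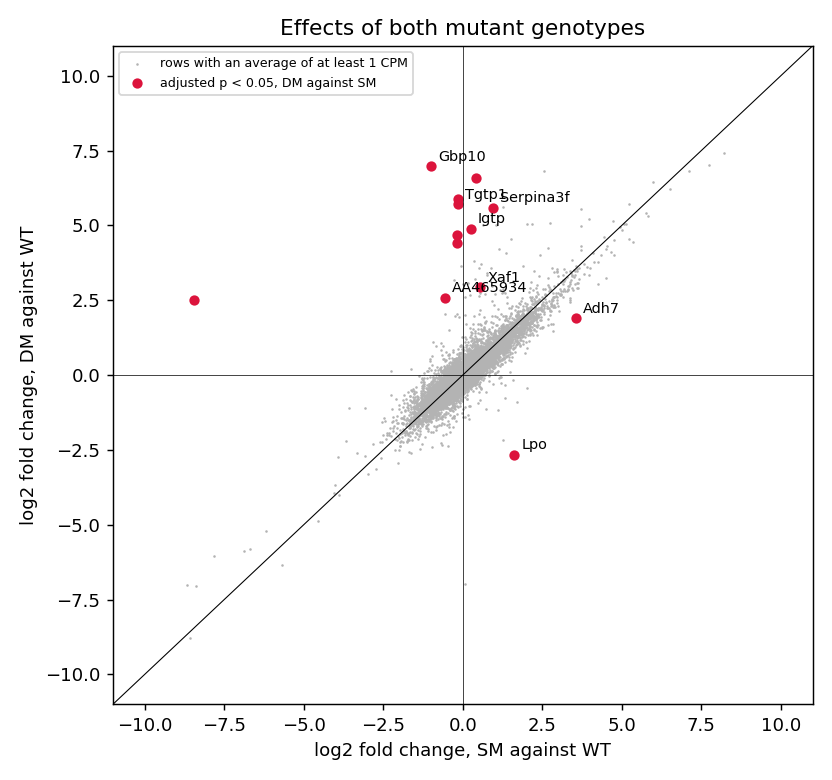
Log2 fold change of DM against WT (vertical axis) against that of SM against WT (horizontal axis) for rows with an average of at least 1 CPM, with rows past the threshold in DM against SM in red and the line of equal values. Most rows lie along the line (correlation 0.887), while Tgtp1 and Igtp lie above it and Lpo below it.

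With miR-21 also missing, interferon-inducible genes were higher than with loss of Pkd2 alone, and few single genes passed. Matrix and stromal genes were slightly lower as lists. Of 30431 rows 24 passed in DM against SM in the authors' deposited table, 17 higher and 7 lower. An unadjusted p below 0.05 was found for 1140 rows, 3.75% of all rows, and for 3.01% of rows with at least 1 CPM. Both shares are below what a cut at 0.05 gives when nothing differs, so the 1140 rows are no sign of a wider difference. Of the 24 rows 6 had no gene name and 11 had an average below 1 CPM, and 13 passed when only rows with at least 1 CPM were tested. At the median implied SE of 0.26 a log2 fold change of about 1.10 was needed to pass. The interferon-inducible GTPase genes Gbp10 at 7.99 (implied SE 1.84, adjusted p = 0.0245), Tgtp1 at 5.88 (implied SE 1.27, adjusted p = 0.0122), Gbp6 at 4.86 (implied SE 1.16), Igtp at 4.64 (implied SE 1.06) and Tgtp2 at 4.58 (implied SE 1.10) rose in the authors' deposited table, as did the serpin gene Serpina3f at 4.65 (implied SE 1.0). Tgtp1 and Tgtp2 are near-identical neighbours and the Gbp genes are close paralogs, so reads may be split among them and their single values are uncertain. The lactoperoxidase gene Lpo fell, at -4.28 (implied SE 0.51, adjusted p = 1.58e-12), with Pcdhgb8 at -2.28 (implied SE 0.54) and the alcohol dehydrogenase gene Adh7 at -1.67 (implied SE 0.39) in the authors' deposited table.

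The interferon response list was higher in DM than in SM (median 0.85, camera adjusted p = 7.94e-22), while 0 of its 23 members passed over all genes in the authors' deposited table and 9 were higher adjusted over the list alone. Lower as lists in DM against SM were fibroblast and mural cell genes (median -0.31, camera adjusted p = 1.68e-05), fibrillar matrix genes (median -0.27, camera adjusted p = 2.72e-05), endothelial genes (median -0.31, camera adjusted p = 1.85e-04), principal cell genes (median -0.15, camera adjusted p = 0.00164), blood genes (median -0.76, camera adjusted p = 0.0133) and neutrophil genes (median -0.53, camera adjusted p = 0.0184). These blood and neutrophil values rest on the 4 of 9 and 5 of 12 members above 1 CPM, and the medians over all members were 0 and -0.60. Wnt, Notch and Hedgehog targets were lower (median -0.22, camera adjusted p = 0.0121), and fatty acid oxidation (median 0.23, camera adjusted p = 0.00559) and oxidative phosphorylation genes (median 0.20, camera adjusted p = 0.0151) were higher, calls that were lost at a preset correlation of 0.05 with adjusted p = 0.0602, 0.0532 and 0.0879. In each of these lists 0 members passed over all genes in the authors' deposited table. Adjusted over the list alone, 1 fibroblast and mural cell gene and 1 principal cell gene were lower and 0 members of the other lists passed. The list tests count genes at an assumed correlation, so their p-values do not measure the spread between animals.

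Reported miR-21 targets did not pass as a list in DM against SM (median -0.03, camera adjusted p = 0.759), and 0 of 38 passed in the authors' deposited table, 0 adjusted over the list alone. The 4 with the smallest unadjusted p in the authors' deposited table were Reck at 0.45 (implied SE 0.20), Cdc25a at 0.42 (implied SE 0.23), Tgfbr2 at -0.45 (implied SE 0.25) and Fasl at 1.85 (implied SE 1.03), each with an adjusted p of 1. Lists of tubular injury (camera adjusted p = 0.485), macrophage (0.529), mitotic (0.846), S phase (0.177), p53 (0.629), proximal tubule (0.759), thick ascending limb (0.0829), distal convoluted tubule (0.111), intercalated cell (0.066), podocyte (0.122), glycolysis (0.726), cAMP response (0.565), cilium (0.355), sex-linked (0.486), T, B and NK cell (0.0598, and 7.52e-11 with all rows as background) and perturbed loci (0.0784) genes did not pass in DM against SM, with 0 members past the threshold in the authors' deposited table. Adjusted over the list alone, 3 T, B and NK cell genes, 1 distal convoluted tubule gene and 1 perturbed locus were higher, and 0 members of the others were called.

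Genes with a miR-21-5p site in the 3′ UTR were compared with genes without in DM against SM, since loss of a microRNA is known to raise its targets. The 1088 genes with the 7-base site had a median log2 fold change of -0.01, and the difference from the 12359 genes without it was -0.00959. Control words gave a median difference of -0.0280, with most words between -0.0491 and -0.0110. In all, 6 of 419 control words lay at or above the miR-21 site (2-sided rank among permutations of the site, p = 0.0333). Genes with the site were thus not higher in DM than genes without it, and their difference was only less negative than for most control words. Their median 3′ UTR length was 2813.5 bases, against 1192 over all genes searched, and genes were not matched on length. The rank was p = 0.152 among permutations with 8mer sites only and p = 0.571 among permutations for genes above the median expression. Measured as a distance from 0 instead of a rank, the version computed first, the same data gave p = 0.986 among permutations of the site.

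**Figure D3:**
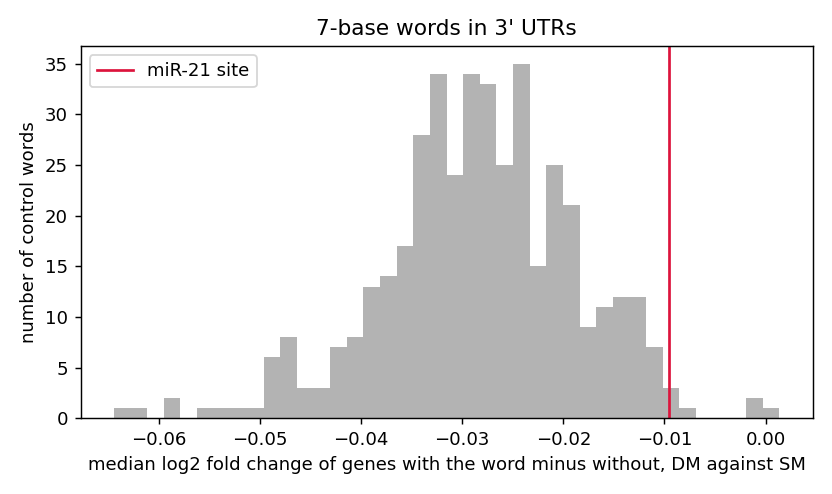
Number of control words (vertical axis) by the difference in median log2 fold change, DM against SM, between genes with and without the word in the 3′ UTR (horizontal axis). The miR-21 site (red line) lies at -0.00959, with 6 of 419 control words at or above it.

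Several of the genes that differed between DM and SM lay on chromosome 11, which carries the miR-21 gene. Within 10 Mb of it, 19 of 217 genes had an unadjusted p below 0.05 in the authors' deposited table of DM against SM, 8.76% against 2.80% elsewhere, and 180 windows of as many genes elsewhere placed that share at percentile 96.1. Rows without a gene name, 6 of the 24 past the threshold, could not be placed. Of all 30431 rows 30121 lay outside the window or had no position. Of the 24 rows past the threshold 4 lay in that window in the authors' deposited table. They were Lpo (chromosome 11, 87806428 to 87828289), Epx (87864000 to 87875536, log2 fold change -5.79, implied SE 0.97), AA465934 (83291699 to 83294632, 3.14, implied SE 0.51) and Gm15698 (88964658 to 88966931, 3.87, implied SE 0.67) in the authors' deposited table, Epx and Gm15698 with an average below 1 CPM. Epx, AA465934 and Gm15698 fall outside the rule for named genes and were chosen after their values were seen.

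**Figure D4:**
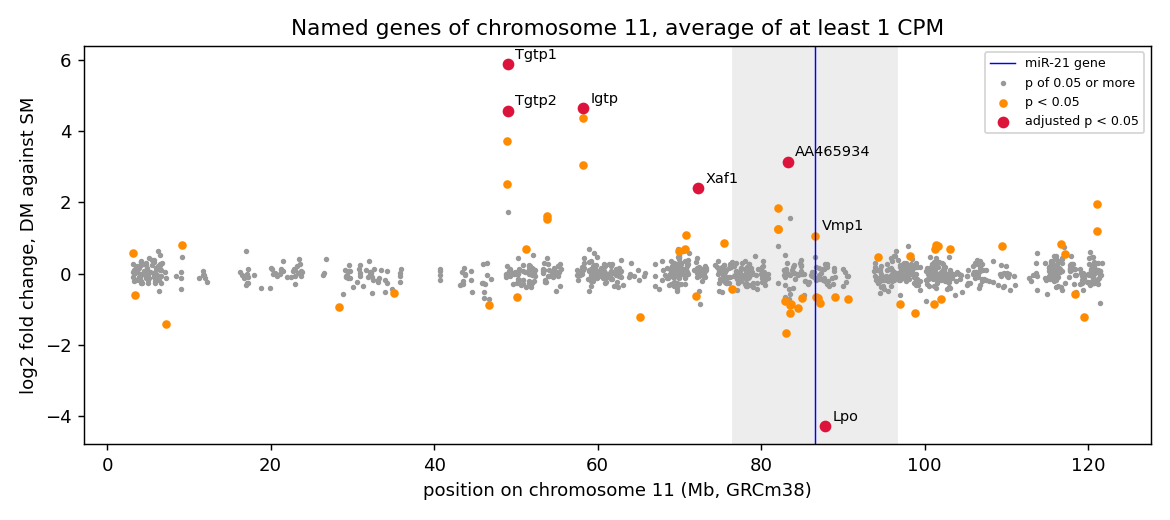
Log2 fold change, DM against SM (vertical axis), of named genes of chromosome 11 with an average of at least 1 CPM by position in Mb (horizontal axis), with the window of 10 Mb around the miR-21 gene shaded. In the window 19 of 217 genes have an unadjusted p below 0.05.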

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

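The explanations of the hepatocyte and interferon patterns, and linked DNA around miR-21, were tested only after the results were seen, except other neighbouring tissues, and the remaining tests had their bounds written before their values were computed. Rows with a different effect in the 2 mutant genotypes numbered 24 in the authors' deposited table of DM against SM, which tests the difference of both effects against WT directly. Higher in DM were Gbp10 (7.99), Gm4841 (6.02), Tgtp1 (5.88), Gbp6 (4.86), Serpina3f (4.65), Igtp (4.64), Tgtp2 (4.58), 3110035E14Rik (4.06), Gm15698 (3.87), AA465934 (3.14) and Xaf1 (2.39), as log2 fold changes of the authors' deposited table. Lower in DM were Epx (-5.79), 1700007B14Rik (-4.72), Trpv3 (-4.49), Lpo (-4.28), Gm8615 (-4.14), Pcdhgb8 (-2.28) and Adh7 (-1.67) in the authors' deposited table, and the genes outside the rule for named genes were chosen after their values were seen. Median log2 fold changes of the lists that differed were 0.854 for interferon response, 0.233 for fatty acid oxidation, 0.20 for oxidative phosphorylation, -0.152 for principal cell, -0.219 for Wnt, Notch and Hedgehog targets, -0.275 for matrix, -0.308 for fibroblast and mural cell, -0.315 for endothelium, -0.528 for neutrophil and -0.761 for blood genes, over members above 1 CPM (4 of 9 for blood, with 0 over all 9).

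Interferon response genes had a log2 fold change above 0 in DM against SM for 23 of 23 members in the authors' deposited table, of which 0 passed over all genes and 9 adjusted over the list alone. A variant linked to the miR-21 gene that acts on genes of other chromosomes was not tested and stays open. Linkage of the members themselves to that gene is argued against only for the 22 of 23 on other chromosomes, which had a median log2 fold change of 0.834. It stays open for genes past the threshold that are outside the list. Of these Xaf1 lies on chromosome 11 (72301629 to 72313733), as does the miR-21 gene. No sign of more macrophages was seen in DM, since the macrophage list had a median of -0.0531 (mean -0.03, SD over 26 members 0.475). That SD is a spread over genes and not over animals, and the median implied SE of a member was 0.31, so a moderate rise is not excluded. More lymphocytes stay open at a list median of 0.416 over 6 members above 1 CPM and 0.887 over all 21 (adjusted p = 0.0598, and 7.52e-11 with all rows as background), and a strong response in some animals only stays a candidate explanation, since the implied SE of the list lay at the 100th percentile of lists matched on expression, but so did those of the mitotic, matrix, tubular injury and sex-linked lists, so the value is not particular to it. Without values per library the 3 DM animals cannot be looked at singly, and effects of the miR-21 genotype itself and of the sex of the animals remain open and untested.

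Genes with an unadjusted p below 0.05 in DM against SM made up 8.76% of genes within 10 Mb of the miR-21 gene and 2.80% elsewhere, although windows of 40 genes there, without interferon-induced families, held at most 6 (p = 0.342 for the highest window in permutations of the genes). A cluster that also differs between SM and WT was not seen, since the same window lay at percentile 74.7 in SM against WT. There 33.2% of genes elsewhere had p below 0.05, so a small cluster could be hidden. Linked DNA carried with the null allele may contribute and stays open, although the window's percentile of 96.1 stayed under its bound. That percentile ranks genes by unadjusted p. Of 30431 rows, the 30121 outside the window or without a position held 20 of the 24 rows past the threshold in DM against SM. Whether the window held more of them than other windows was not tested. In DM against WT 39.2% of its genes had p below 0.05, against 31.4% elsewhere (percentile 95). In DM against SM, leaving out the families picked as interferon-induced lowered the share to 6.93% (14 of 202 genes) but hardly moved its percentile, at 96.4. With p below 0.05, Ccl7 (1.24), Ccl12 (1.25) and Ccl8 (1.84) were higher in DM among the genes left out, and Slfn8 (-1.66) and Ccl6 (-0.87) lower. These families stay open as an explanation since the bound was missed with and without them. Loss of miR-21 itself stays open and untested.

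Hepatocyte transcripts were lower in both mutants than in WT, with an implied SE at the 100th percentile of matched lists, as for several other lists. Liver tissue or liver RNA in some wild-type libraries may explain it, but the list median of -1.41 fell between the bounds set, and in WT Alb stood at 132 CPM, Ttr at 86.4, Trf at 64.1, Fga at 27.8, Hp at 16.1, Apoa1 at 12.1, Fgb at 9.59, Fgg at 6.98 and Serpina1b at 5.45. Loss of proximal tubule cells may contribute, since the hepatocyte median lay -0.249 from the proximal tubule median over the 29 members above 1 CPM (-1.97 against -1.16 over all 40), whereas 20 of 40 hepatocyte markers fell further than the proximal tubule gene with the largest fall, Gatm at -1.82, a count added after the values were seen. Uneven dissection of other tissues stays open, with a lowest median of -0.993 among the fat and muscle lists, and the adrenal gland list, with 2 members above 1 CPM, had medians over all 14 of -1.50 in SM against WT and -2.71 in DM against WT. None of the hepatocyte markers is in another fixed list, and how many of them the kidney itself expresses was not measured.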

How the results depend on the processing

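Only the least fold change, 8mer sites and genes above the median expression were planned, and the other settings were added after the data were seen. Counts of called rows stayed within 1.5 times in SM against WT (2900 to 4188, from 4248) and in DM against WT (2864 to 4045, from 4100) under all settings run. In DM against SM the count fell from 24 to 13 when only rows with at least 1 CPM were tested, since 11 called rows lay below that level, and was 17 to 24 otherwise, with 17 without interferon-induced families and 20 without genes within 10 Mb of miR-21. Lists called numbered 46, 50 with all rows as background and 40 at a preset correlation of 0.05, and no list that passed turned its direction. With all rows as background T, B and NK cell genes passed in DM against SM (adjusted p = 7.52e-11) and DM against WT (3.65e-07), interferon response (0.0123) and fibroblast and mural cell genes (0.0115) in SM against WT and podocyte genes in DM against WT (0.0368), while blood genes no longer passed in SM against WT (0.17). The miR-21 site call was lost with 8mer sites (0.152), with genes above the median expression (0.571) and as a distance from 0 (0.986), and held without words with CG (0.0111); the cause was not tested. Rows shared in direction numbered 3037, 2667 with at least 1 CPM and 2710 with names only. Named genes kept their side of the threshold with at least 1 CPM and with names only, wherever they were tested.

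No paired analysis was possible because no value per library was analysed and the animal numbers differ between groups. For the same reason other normalizations, DESeq2, pseudocounts, sex as a covariate, an estimated list correlation, leaving out each library, a split of the WT libraries and other splits of the samples were not run, so no result shows whether a single animal decides it. The likelihood ratio test and the fit of all 10 libraries are those of the deposited tables. Depth is unknown, and a gene at the median implied SE in DM against SM needed a 2.14-fold change to pass.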

Other observations

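The test of linked DNA around Pkd2 had its bounds written before its value was computed, and the other values here were chosen after the data were seen. Of the adrenal gland and pancreas markers 2 of 14 and 1 of 14 were above 1 CPM, against 12 of 12 fat and 5 of 13 skeletal muscle markers. Adrenal gland markers fell for 3 of 14 and rose for 1 in SM against WT in the authors' deposited table, and fell for 4 and rose for 1 in DM against WT; adjusted over the list alone 4 and 8 fell and 1 rose in each (adjusted p = 0.201 and 0.013 with all rows as background). Among fat markers 2 of 12 fell in SM against WT in the authors' deposited table, 3 adjusted over the list alone (camera adjusted p = 0.124) and 0 in DM against WT by either count. Skeletal muscle markers fell for 2 of 13 (3 adjusted over the list alone) with 1 higher in SM against WT and for 1 with 1 higher in DM against WT, and 1 of 14 pancreas markers fell in each comparison with WT, in the authors' deposited tables.

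Linked DNA around the floxed Pkd2 allele was a candidate explanation for part of the difference from wild type, tested by the share of genes with p below 0.05 within 10 Mb of Pkd2. That share lay at percentile 34.6 of windows elsewhere in SM against WT and at 65.1 in DM against WT, so it did not stand out. Elsewhere 33.3% of genes had p below 0.05 in SM against WT, so a few linked genes could not be seen. Linked DNA there stays open.

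A scan of 1303 windows of 40 neighbouring genes, without the interferon-induced families picked by symbol, was made in DM against SM. Its highest count was 8 genes with p below 0.05 in the authors' deposited table, in 3 overlapping windows on chromosome 8 from 70723720 to 75224113, where 2.50% of genes passed genome-wide (p = 0.0058 for the highest window in 10000 permutations of the genes). The genes were Pde4c, Arrdc2, Ocel1, Tmem221, Fam129c, Glt25d1, B3gnt3, Tpm4, Fam32a, Klf2 and Hmox1, and permuting genes ignores that neighbours can be expressed together.

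Of 3273 rows called in SM against WT with at least 1 CPM, 72.9% had a smaller change in DM, and of 3002 called in DM against WT 49.1% had a smaller change in SM, from the authors' deposited tables. Rows picked for a change in a group tend to be overstated in that group, so both shares are raised by the choice. Less the error of the values, the slope of DM on SM was 0.950 and that of SM on DM 0.978.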
